A study of Mus musculus with 12 samples.

How the data were processed

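Epididymal fat of male C57BL/6J mice was profiled for microRNAs by quantitative RT-PCR in 12 pooled samples, 3 pools from 12 mice in each of 4 groups. Per the labels, total RNA was isolated from about 22 mg of fat pad with the miRNeasy kit and its integrity was measured on a Bioanalyzer. The RNA integrity values, the PCR platform, the reverse transcription chemistry, the rule that set the threshold cycle and any earlier selection of assays are not given in the sources used here. Expression of genes of the mTOR network, which the series title also names, was not analysed here.

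Per the file headers, the authors deposited threshold cycles (Ct) before normalization, and these were the values tested here. A lower Ct stands for more template, and each cycle stands for a 2-fold step when the PCR doubles its product in every cycle. The table listed 507 assays, of which 1 row repeated another and was dropped, leaving 504 microRNA assays and 2 reference RNAs, U6-snRNA and RNU-43. In 39 assays 57 values were missing, and 467 assays, 466 of them microRNAs, were measured in all 12 samples. The number of pools limits the precision: the median standard error of a log2 fold change was 0.43 against the control group for WL and UL and 0.44 for UT.

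Per the file headers, the deposited normalized values are ratios equal to 2 to the power of minus delta Ct. Tested on the values, Ct minus the log2 of the deposited ratio was constant within each sample (24.74 to 25.46, varying by at most 0.01 within a sample), so these ratios grow with later cycles, opposite to the header. What the constant stands for is not given in the sources used here. A further deposited table holds the authors' fold changes as ratios of group means. Its column for UT matched the mean of UT 1, UT 2 and UT 3 over the control mean in 507 of 507 assays (tolerance 0.0001 on the log2 scale; 220 sets of 3 samples were tried). Its column for UL matched the mean of UT 2, UT 3 and UL 1 in 507 of 507 assays, and its column for WL matched the mean of UT 3, UL 1 and UL 2, which includes no WL pool. Against ratios recomputed from the named group's own pools, 24.9% of assays in the UL column and 43.8% in the WL column lay on the other side of 1. The fold changes reported here come from the Ct values and have the opposite sign to the deposited normalized values.

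For each sample, Ct was subtracted from the sample's mean Ct over the 466 microRNAs measured in all samples. The result is called the relative level, in cycles on the log2 scale. Higher means an earlier Ct than the average microRNA, and more template if the assays amplify alike. The filter, fixed before the data were examined, kept microRNAs with Ct under 35 in at least 3 samples and removed 0 of 504. Group differences were tested with limma 3.58.1 (lmFit and eBayes; R 4.3.3) in a single model of the 4 groups over all 12 pools, with Benjamini-Hochberg adjustment over the 504 microRNAs and a threshold of 0.05 on the adjusted p. Missing values were left missing, so the number of pools behind a fold change is given where it is under 3. The limma tests were two-sided and treated the pools as independent. Litters did not enter the model, although early exposure came through the dam. If pools of a group shared litters, the SE could be too small. The prior degrees of freedom of the variance were 3.36. The comparisons were each high-fat group against the control diet, the high-fat groups against each other, the mean of UT and UL against the control diet (early exposure) and an F test over the 4 groups. The script was tested on simulated data for WL against CD, with 200 of 504 microRNAs changed, in 20 simulations. It recovered 39.5% of 2-fold, 80.5% of 4-fold, 91.4% of 8-fold and 96.3% of 16-fold changes, and 2.5% of the calls were false. When few microRNAs change, the adjustment is stricter than in this simulation. These shares therefore do not carry over to comparisons with few calls, where changes of these sizes may go uncalled.

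The microRNAs named were chosen by a rule fixed before the data were examined. It took, for each high-fat group against control, every microRNA past the threshold, filled up to 20 with the smallest unadjusted p, and the 4 members of each list with the highest mean level. Other names are given as chosen after the values were seen. Before the data were examined, 22 lists with 381 entries were written down: mTOR-targeting, pro-adipogenic, anti-adipogenic, raised and lowered in obese mouse fat, thermogenic fat, early-life nutrition in fat, lipid and insulin signalling, leukocyte, erythroid, muscle, liver, endothelial, stromal and smooth muscle, epithelial, testis and epididymis, neural, the Dlk1-Dio3 and Sfmbt2 imprinted clusters, the let-7 and miR-30 families, and the clusters of miR-17 to miR-92a and their paralogs. No measured assay matched 77 of the entries; older names that now carry an added letter were matched by a rule added after the names in the table were seen. Lists were tested on the 466 microRNAs measured in all samples with camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over 66 tests (22 lists and 3 contrasts), and with an estimated correlation and fry beside it.

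Alternatives planned before the data were examined were RNU-43 as the reference RNA, the deposited normalized values with a pseudocount of 1 or 16, no filter, a filter of Ct under 32, a fit of the compared groups only, the replicate number as a block, each pool left out in turn, and, for lists, an estimated correlation and fry. U6-snRNA was missing in 2 pools and was not used as a reference. Alternatives chosen after seeing the data were microRNAs measured in all samples only, centring on the median, the authors' constant per sample, limma sample weights, omission of both UT 3 and WL 3, a covariate for UT 1 to 3 and WL 3, an exchange of values between 2 pairs of assays in those 4 pools, and subtraction of the median deviation of neighbouring assays (3 on either side in the order of the deposited accession numbers). Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for the tables and figures.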

Results

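MicroRNA levels were measured in epididymal fat, a visceral fat depot, of adult male mice that had met a high-fat diet in different periods of life. The control group (CD) ate a diet with 10% of its energy from fat, and the high-fat diet held 45%. Exposure through the dam in utero defined the group UT, exposure from mating to weaning the group UL, and exposure from mating to the end of the experiment at 23 weeks the group WL. Each group was represented by 3 pools. The assays measured per pool ranged from 493 in UT 2 to 507 in UL 1, and the median Ct ranged from 24.59 in UT 2 to 25.28 in UT 3. Single values lay between 15.05 and 37.04 cycles, and 47 assays had a mean Ct of 30 or later.

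Averaged over the pools with a value, miR-712-5p stood 9.41 cycles above the average microRNA, miR-690 9.08 (9 pools) and miR-714 8.62. They were followed by let-7b-5p at 8.48, let-7c-5p at 8.34, miR-706 at 8.02 (10 pools) and miR-21a-5p at 7.94. The adipogenic miR-26a-5p stood at 7.77 and the endothelial miR-126a-3p at 7.47. This order is one of Ct between assays, whose efficiencies were not measured here, so it need not be an order of amounts. In the 6 let-7 hairpins with both arms measured, the passenger 3p arm came later than the 5p arm in 6 of 6, by a median of 7.36 cycles. The small nuclear RNA U6 lay at 9.56 ± 0.15 in CD (SD, n = 3), 9.60 ± 0.11 in UT (n = 2), 9.55 ± 0.12 in UL (n = 3) and 9.30 ± 0.61 in WL (n = 2). The small nucleolar RNU-43 lay at 7.48 ± 0.31 in CD, 6.74 ± 0.32 in UT, 7.12 ± 0.33 in UL and 7.47 ± 0.29 in WL (SD, n = 3 each). Scaling to RNU-43 therefore moved the median log2 fold change of all microRNAs from -0.01 to 0.73 in UT and from -0.07 to 0.30 in UL, and fold changes below are relative to the average microRNA. Pools differed in their spread around the group mean, from an SD of 0.48 cycles in UL 3 to 1.04 in UT 2 and 1.19 in WL 3. The first principal component, with 25.9% of the variance, set WL 3 and UT 2 apart from the other pools.

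The first comparison asked which microRNAs differed in fat after a high-fat diet that lasted from mating to 23 weeks. In WL, 3 microRNAs passed the threshold against the control diet, 3 higher and 0 lower. MiR-494, of the Dlk1-Dio3 imprinted cluster, had a relative level of 5.21 ± 0.14 in WL and -6.35 ± 5.23 in CD (SD, n = 3 each), a log2 fold change of 11.56 (SE 1.99, limma adjusted p = 0.0374), and all 3 WL pools lay above all 3 CD pools. MiR-291b-5p, of the embryonic stem cell cluster miR-290 to miR-295, lay at -2.90 ± 0.58 in WL (n = 3) and at -11.12 in the single CD pool that gave a value, at Ct 35.92, a log2 fold change of 8.22 (SE 0.55, limma adjusted p = 0.000452). MiR-135b-3p lay at -6.73 ± 0.62 in WL (n = 3) and at -11.80 in the single CD pool with a value, at Ct 36.69, a log2 fold change of 5.07 (SE 0.52, limma adjusted p = 0.000828). For these last 2 the control group has 1 value, past Ct 35, and no spread of its own: the SE comes from the other groups, and the lone pool is assumed to vary as they do, here and in the comparisons below.

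Among microRNAs that did not pass in WL, miR-484 lay at 3.10 ± 0.22 in WL and 1.76 ± 0.13 in CD (n = 3 each), a log2 fold change of 1.34 (SE 0.28, limma adjusted p = 0.0572). The 3p assay of miR-378, which lies in the gene of the coactivator Ppargc1b, had a log2 fold change of 1.48 (SE 0.36, limma adjusted p = 0.133), and miR-483, which lies in Igf2, had 1.19 (SE 0.33, limma adjusted p = 0.287). Both lay higher in 3 of 3 WL pools than in every CD pool. MiR-20b-5p had a log2 fold change of 6.42 (limma adjusted p = 0.0572) with a value in a single CD pool. Log2 fold changes above 0 were also listed for miR-351-3p (1.18), miR-302b-5p (1.91), miR-302d-3p (3.05), miR-291b-3p (1.95), miR-485-3p (1.00), miR-503 (2.76) and miR-376b-5p (3.62). Log2 fold changes below 0 were listed for miR-693-5p (-1.63), miR-694 (-2.33), miR-154-5p (-1.73), miR-494-5p (-0.95), miR-340-3p (-1.07) and miR-702-3p (-1.66). These 13 had limma adjusted p between 0.303 and 0.407. MiR-494-5p, from the hairpin of miR-494, lay lower in 3 of 3 WL pools than in every CD pool.

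In WL, 36 of 504 microRNAs had an unadjusted p under 0.05, and the ranges of the WL and CD pools did not overlap in 53 of 481 microRNAs complete in both (11%, where chance gives 10%). Over 24 other settings the log2 fold change of miR-494 ranged from 3.36 to 14.58, and the call was kept in 9 (limma adjusted p up to 0.608). Its Ct was 25.11 in CD 1, 34.04 in CD 2 and 34.37 in CD 3; without CD 1 the log2 fold change was 14.58 (adjusted p = 1.65e-08), and without CD 2 or CD 3 the adjusted p was 0.125 or 0.0686. MiR-494, miR-291b-5p and miR-20b-5p, all missing in UT 1 and UT 2, span 3 places in the order of the assays' accession numbers. The count fell to 1 without UT 3, when miR-291b-5p and miR-494 had no UT value left and could not be fitted, rose to 6 without CD 3, and was 0 among microRNAs measured in all 12 pools. With the median deviation of neighbouring assays subtracted, an alternative chosen after seeing the data, the log2 fold change in WL was 4.68 (SE 0.62, adjusted p = 0.039) for miR-291b-5p, 4.71 (SE 0.57, adjusted p = 0.0101) for miR-135b-3p and 10.05 (SE 2.64, adjusted p = 0.446) for miR-494; over all settings the adjusted p of the first 2 reached 0.0487 and 0.209.

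**Figure D1:**
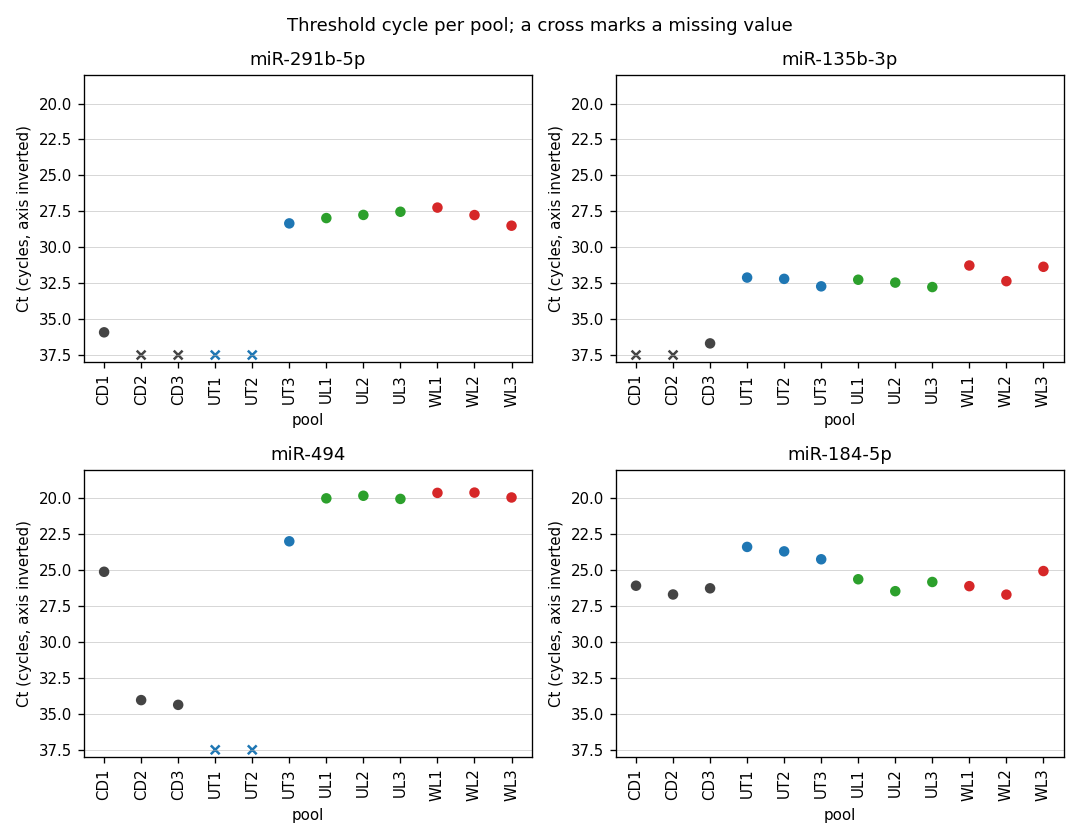
Threshold cycle (Ct, y axis, inverted so that more template lies higher) of miR-291b-5p, miR-135b-3p, miR-494 and miR-184-5p in each of the 12 pools (x axis), with points coloured by group and crosses at the bottom for missing values. MiR-494 and miR-291b-5p were late or missing in CD 1 to 3 and missing in UT 1 and UT 2, while miR-184-5p came earliest in the 3 UT pools.

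The second comparison asked what remained in adult fat of a high-fat diet that ended at weaning. In UL, 3 microRNAs passed against the control diet, 3 higher and 0 lower, and they were the same 3 as in WL. MiR-494 lay at 4.98 ± 0.16 in UL (n = 3), a log2 fold change of 11.33 (SE 1.99, limma adjusted p = 0.0435). MiR-291b-5p lay at -2.81 ± 0.18 in UL (n = 3), a log2 fold change of 8.30 (SE 0.55, limma adjusted p = 0.00042, 1 CD pool), and miR-135b-3p at -7.56 ± 0.31 (n = 3), a log2 fold change of 4.24 (SE 0.52, limma adjusted p = 0.00376, 1 CD pool). The 2 contrasts share their control pools: with unchanged groups simulated against the same controls, the mean overlap was 0.01 and the highest 1 in 100 simulations, and independent lists would share 0.018. Unchanged groups give hardly any calls at this threshold, so that simulation says little about control values that stand out. With 3 control pools the controls could not be split. All 3 shared calls rest on the same control values in both contrasts, for miR-291b-5p and miR-135b-3p on 1 CD pool each. The overlap may therefore come from sharing them.

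Among microRNAs that did not pass in UL, miR-20b-5p had a log2 fold change of 6.46 (SE 1.11, limma adjusted p = 0.0685, 1 CD pool) and miR-17-3p, of the cluster of miR-17 to miR-92a, had 1.51 (SE 0.43, limma adjusted p = 0.46). MiR-351-5p and miR-503, which are encoded near each other on the X chromosome, had log2 fold changes of 1.56 and 2.55. The stem cell microRNAs miR-291b-3p, miR-302b-5p, miR-302c-5p and miR-302d-3p had 2.09, 1.80, 1.53 and 2.52, with miR-302d-3p late in CD 1 and CD 2 (Ct 33.12 and 35.04) and at 30.1 in CD 3. Values of 3.28 were listed for miR-376b-5p, 0.68 for miR-484, 0.73 for miR-351-3p, 0.78 for miR-212-5p, 0.65 for miR-486 and 1.15 for miR-34a-3p. Below 0 were miR-698-3p (-1.31), miR-693-5p (-0.97) and miR-697 (-0.75). These 15 had limma adjusted p between 0.519 and 0.995. In UL, 14 microRNAs had an unadjusted p under 0.05, and ranges did not overlap in 39 of 495 microRNAs (7.9%, where chance gives 10%). The call for miR-494 was kept in 10 of 24 other settings (adjusted p up to 1; 1.89e-08 without CD 1, 0.145 without CD 2 and 0.0698 without CD 3). Over these settings the log2 fold change of miR-494 in UL ranged from 3.36 to 14.35. The count of microRNAs that passed was 1 without UT 3, 5 without WL 3, 6 without CD 3 and 0 among microRNAs measured in all 12 pools. With neighbouring assays subtracted, miR-291b-5p had 4.82 (SE 0.62) and miR-135b-3p 3.92 (SE 0.57), each with an adjusted p of 0.0324, the highest over all settings, and miR-494 had 9.28 (SE 2.64, adjusted p = 0.696).

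The third comparison asked what remained of exposure in utero alone. In UT, 7 microRNAs passed against the control diet, 6 higher and 1 lower. MiR-184-5p lay at 0.98 ± 0.23 in UT and -1.52 ± 0.33 in CD (SD, n = 3 each), a log2 fold change of 2.50 (SE 0.43, limma adjusted p = 0.0165), with 3 of 3 UT pools above every CD pool. MiR-291b-3p lay at -6.95 ± 0.46 in UT and -9.89 ± 1.40 in CD, a log2 fold change of 2.94 (SE 0.62, limma adjusted p = 0.0423), again higher in 3 of 3 pools. Its partner arm miR-291b-5p had a log2 fold change of 7.84 (SE 0.67, limma adjusted p = 0.00266) that sets 1 UT pool against 1 CD pool, with the spread taken from UL and WL. MiR-135b-3p lay at -7.59 ± 0.09 in UT (n = 3), a log2 fold change of 4.21 (SE 0.52, limma adjusted p = 0.00397, 1 CD pool).

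The other 3 calls in UT belonged to 2 pairs of assays. MiR-592-3p lay at 0.19 ± 0.33 in UT and -5.23 ± 0.57 in CD, a log2 fold change of 5.42 (SE 1.12, limma adjusted p = 0.0402). MiR-758-5p, of the Dlk1-Dio3 cluster, lay at -4.66 ± 0.41 in UT and 0.06 ± 0.71 in CD, a log2 fold change of -4.71 (SE 0.96, limma adjusted p = 0.0402). MiR-676-3p lay at 1.55 ± 0.14 in UT and -2.49 ± 0.94 in CD, a log2 fold change of 4.04 (SE 0.79, limma adjusted p = 0.0373), while the opposite arm miR-676-5p lay at -1.97 ± 0.61 and 1.47 ± 0.26, a log2 fold change of -3.44 (SE 0.86, limma adjusted p = 0.0763). WL 3 showed the same shifts. In UT 1 to 3 and WL 3 the mean level of miR-592-3p, 0.26, lay 0.18 cycles from that of miR-758-5p in the other 8 pools, and the level of miR-676-3p, 1.42, lay 0.09 from that of miR-676-5p there. With the values of each pair exchanged in these 4 pools, an alternative chosen after seeing the data, the log2 fold changes in UT were 0.57 for miR-592-3p, 0.13 for miR-758-5p, 0.52 for miR-676-3p and 0.08 for miR-676-5p (limma adjusted p 0.672 to 0.966), and miR-291b-3p had an adjusted p of 0.0719.

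**Figure D2:**
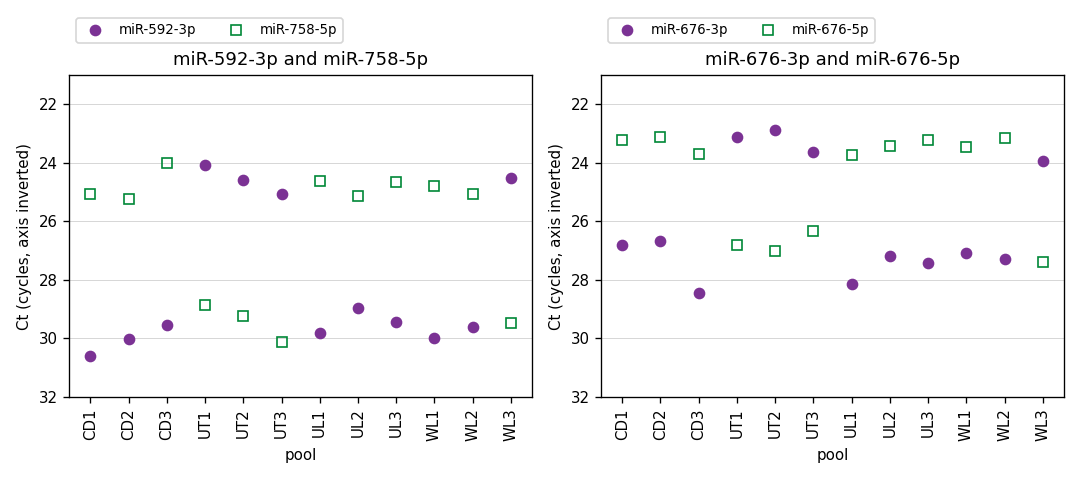
Threshold cycle (Ct, y axis, inverted) of miR-592-3p and miR-758-5p (left) and of miR-676-3p and miR-676-5p (right) in the 12 pools (x axis), 1 point per assay and pool. In UT 1 to 3 and WL 3 each assay lies where its partner lies in the other 8 pools.

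Among microRNAs that did not pass in UT, miR-363-5p had a log2 fold change of 3.47 (SE 0.77, limma adjusted p = 0.0521), and miR-98-5p, of the let-7 family, had -1.43 (SE 0.33, limma adjusted p = 0.057). MiR-126a-5p, an endothelial microRNA, had 1.36 (SE 0.34, limma adjusted p = 0.0766), whereas its opposite arm miR-126a-3p had -1.19 (SE 0.46, limma adjusted p = 0.395). The stem cell microRNAs miR-302b-5p, miR-302c-5p and miR-295-3p had 2.46, 1.79 and 2.25. Further values were 1.42 for miR-351-3p, 1.41 for miR-329-5p, 0.95 for miR-485-3p, -2.24 for miR-377-5p, -1.61 for miR-101a-3p and -2.80 for miR-205-5p. These last 9 had limma adjusted p between 0.0641 and 0.28.

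In UT, 51 microRNAs had an unadjusted p under 0.05, and ranges did not overlap in 67 of 480 microRNAs (14%, where chance gives 10%). UT shared 2 calls each with WL and UL, where simulated unchanged groups gave means of 0.02 and 0.03 and independent lists would share 0.042. The shared calls were miR-291b-5p and miR-135b-3p, each of which rests on the same single CD pool in every contrast. The count fell to 1 without UT 3, 2 without CD 2 or UT 1, 3 without UL 2 or UL 3 and 4 without CD 1 or UL 1, and reached 11 without WL 3, 4 of them from the 2 pairs of assays. With the median deviation of neighbouring assays subtracted, 0 microRNAs passed in UT. The log2 fold changes were 4.83 (SE 0.76) for miR-291b-5p, 3.32 (SE 0.57) for miR-135b-3p, 5.37 (SE 1.19) for miR-592-3p, 4.07 (SE 0.90) for miR-676-3p and -6.77 (SE 1.24) for miR-758-5p, each with a limma adjusted p of 0.0595. MiR-184-5p had 1.43 (SE 0.82, adjusted p = 0.481) and miR-291b-3p 0.92 (SE 0.95, adjusted p = 0.699). The SE of each of the 7 was wider than before, and the log2 fold changes of miR-291b-5p, miR-135b-3p, miR-184-5p and miR-291b-3p were smaller. Over all settings the adjusted p reached 0.979 for miR-592-3p, 0.815 for miR-676-3p and 0.947 for miR-758-5p.

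Of the 22 lists, 4 passed in UT and 0 in WL or UL by camera with its preset correlation. With an estimated correlation each of the 4 had an adjusted p = 0.88, and the count of 4 fell to 0 without CD 1, CD 3, UT 1 or WL 3 and with neighbouring assays subtracted, and to 2 without UT 2 or UL 3. The epithelial list, led by the miR-200 family and miR-205-5p, which keep cells epithelial, had the lowest median log2 fold change, -0.90, with 1 of 14 measured members above 0 (camera adjusted p = 0.0397). MiR-141-3p had -3, miR-200c-3p -2.44 and miR-200b-3p -2.03, each with a limma adjusted p of 0.371 or more, and their lowest pools were UT 1 and UT 3; within the other groups they were lowest in CD 2, UL 2 and WL 1. The list of microRNAs lowered in obese mouse fat had a median of -0.29 over 26 members (camera adjusted p = 0.0397), and 5 of its members, among them miR-141-3p and miR-200c-3p, also stand in the epithelial list. The stromal and smooth muscle list had a median of -0.51 with 0 of 11 members above 0 (camera adjusted p = 0.0469), with miR-143-3p at -1.06, miR-29b-3p at -0.82 (2 UT pools, and so not among the 10 members that camera tested) and miR-199a-3p at -0.50. The testis and epididymis list, mostly X-linked germ cell microRNAs and the miR-34 and miR-449 families, had a median of 0.62 with 12 of 13 members above 0 (camera adjusted p = 0.0469). MiR-742-3p, its member with the highest mean level, had -0.71. The directional test of fry gave adjusted p of 0.595, 0.358, 0.268 and 0.677 in the order named. No member of these 4 lists passed the test over all microRNAs, and 0 passed in UT when adjusted over the list alone.

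**Figure D3:**
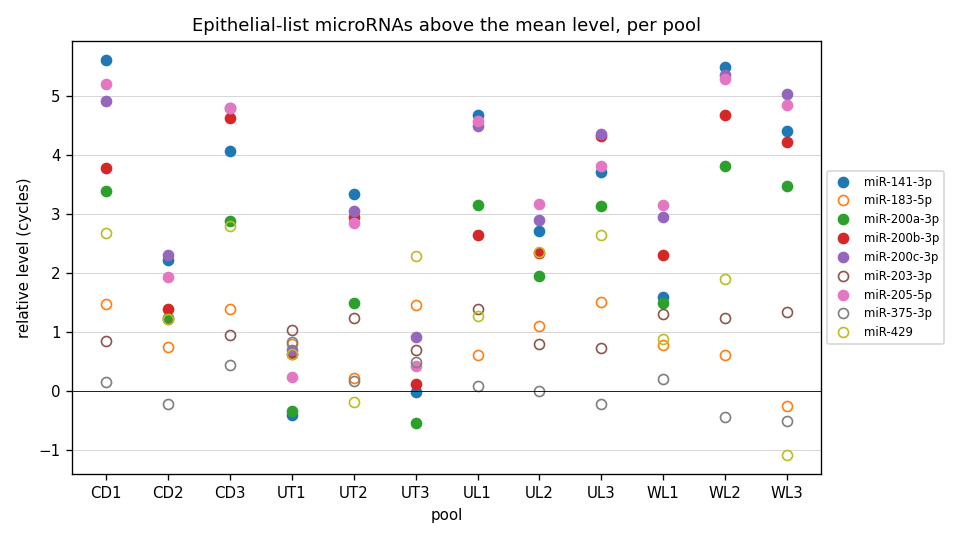
Relative level (y axis, in cycles above the average microRNA) of the 9 epithelial-list microRNAs with a mean level above 0 in each of the 12 pools (x axis), 1 colour per microRNA; filled points mark the 5 whose lowest pools were UT 1 and UT 3, chosen after the values were seen. In UT 2 these 5 lay above their levels in UT 1 and UT 3.

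**Figure D4:**
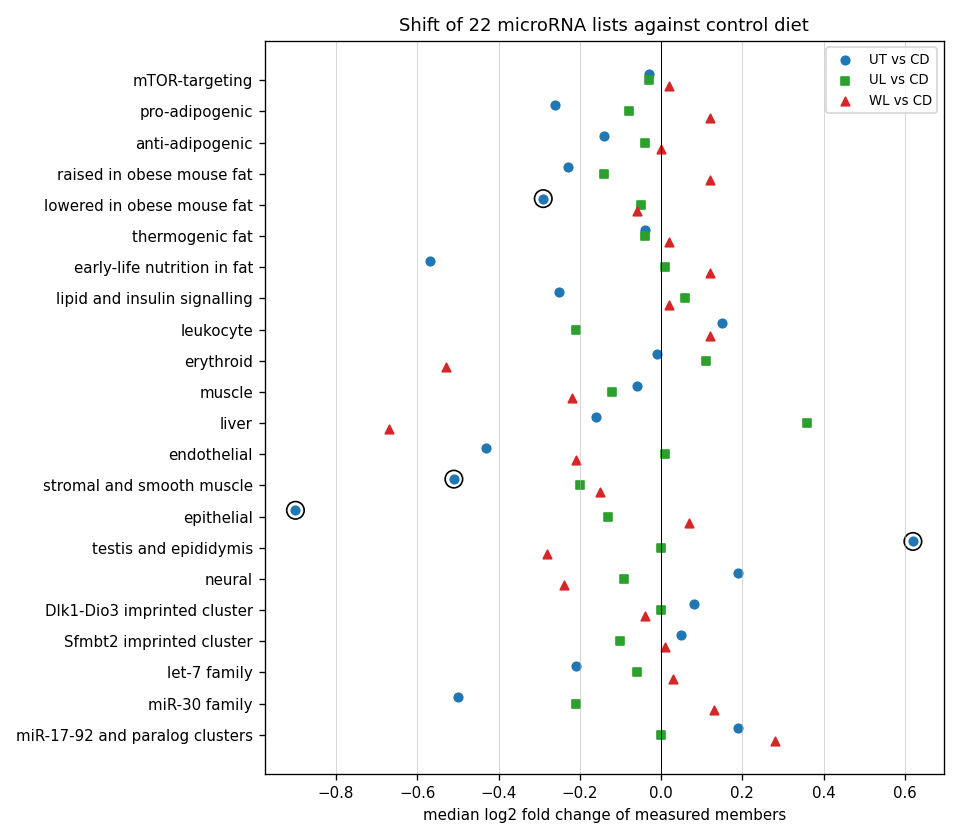
Median log2 fold change against the control diet (x axis) of the measured members of 22 microRNA lists (y axis) in UT, UL and WL, with black rings around the medians of the 4 lists that camera called. The ringed medians all belong to UT, at -0.90, -0.51, -0.29 and 0.62.

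The mTOR-targeting list, of which 23 members were measured, had median log2 fold changes of 0.02 in WL, -0.03 in UL and -0.03 in UT. Of its members, miR-16-5p and miR-99a-5p had the highest mean levels, and the second represses mTOR itself. They had 0.48 and 0.21 in WL, 0.19 and 0.09 in UL and 0.42 and -0.29 in UT. Medians in the same order were 0.12, -0.08 and -0.26 for the pro-adipogenic list, 0.00, -0.04 and -0.14 for the anti-adipogenic list, and 0.02, -0.04 and -0.04 for the thermogenic list. The list raised in obese mouse fat had 0.12, -0.14 and -0.23, and within it miR-146a-5p, a brake on innate immune signalling, had 1.93 in WL (limma adjusted p = 0.663). The list lowered in obese mouse fat had -0.06 in WL and -0.05 in UL. The early-life nutrition list had 0.12, 0.01 and -0.57, and the lipid and insulin signalling list 0.02, 0.06 and -0.25. For the early-life list in UT the mixed test of fry, which asks for change in either direction, gave an adjusted p of 0.0138, with miR-126a-5p at 1.36 and miR-143-3p at -1.06. It was 0.393 or more for every other list and contrast.

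Lists that mark other cells of the fat pad had medians of 0.12 in WL, -0.21 in UL and 0.15 in UT for leukocytes, -0.53, 0.11 and -0.01 for erythroid cells, -0.22, -0.12 and -0.06 for muscle, and -0.67, 0.36 and -0.16 for liver. The endothelial list had -0.21, 0.01 and -0.43 and the neural list -0.24, -0.09 and 0.19. In WL and UL the stromal and smooth muscle list had -0.15 and -0.20, the epithelial list 0.07 and -0.13, and the testis and epididymis list -0.28 and 0.00. The Dlk1-Dio3 imprinted cluster, with 61 members measured, had -0.04, 0.00 and 0.08, with miR-494 called in WL and UL and miR-758-5p in UT, and the Sfmbt2 cluster had 0.01, -0.10 and 0.05. The let-7 family had 0.03, -0.06 and -0.21, the miR-30 family 0.13, -0.21 and -0.50, and the clusters of miR-17 to miR-92a and their paralogs 0.28, 0.00 and 0.19. In UT the miR-30 family had 1 of 9 members above 0 (camera adjusted p = 0.219). Adjusted over the list alone, the 3p assay of miR-378 passed in 3 lists in WL, and miR-483, miR-494 and miR-20b-5p in 1 each. In UL miR-494, miR-20b-5p and miR-17-3p passed, and in UT miR-363-5p passed in 3 lists, miR-126a-5p and miR-758-5p in 2 each and miR-98-5p in 1. Many members stand in several lists (31 of 35 in the pro-adipogenic list), so the lists are not independent. In 14 of the 66 tests the median, the mean and the direction of camera differed in sign, among them 0 of the 4 calls.

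Contrasts between the high-fat groups asked what lactation and the time after weaning added. By limma, 0 microRNAs passed for UL against UT (40 with an unadjusted p under 0.05; smallest adjusted p 0.0607), 0 for WL against UL (27; 0.805) and 0 for WL against UT (79; 0.107). Ranges did not overlap in 13.3%, 9.9% and 19.3% of complete microRNAs, where chance gives 10%. Without WL 3, 8 microRNAs passed for UL against UT, 12 for WL against UT and 1, miR-694, for WL against UL; miR-592-3p, miR-758-5p, miR-676-3p and miR-676-5p, the 2 pairs of assays above, are 4 of the 8 and 4 of the 12. For the mean of UT and UL against the control diet, miR-291b-5p and miR-135b-3p passed, with log2 fold changes of 8.07 and 4.23 (limma adjusted p 0.000514 and 0.00221) against 1 CD pool each, whose spread was not measured (4.83 and 3.62 with neighbouring assays subtracted, adjusted p 0.0322 each), and 30 microRNAs had an unadjusted p under 0.05. Ranges did not overlap in 2.3% of microRNAs, where chance gives 2.4%. The same 2 differed among the 4 groups by the F test of limma (adjusted p 0.00121 and 0.00337), with 50 at an unadjusted p under 0.05. Without UT 3 each count was 1, since miR-291b-5p could not be fitted; without CD 3 they were 6 and 5, and without WL 3 they were 9 and 12, with the 2 pairs of assays giving 4 of each.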

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

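Planned before the data were examined were RNU-43 scaling, the deposited values with a pseudocount, the filters, the fit of the compared groups, the replicate block, each pool left out, the estimated correlation and fry; all others here were chosen after the results were seen. In WL, UL and UT, miR-291b-5p was kept in 23 of 23, 23 of 23 and 22 of 23 settings, and miR-135b-3p in 23 of 24, 24 of 24 and 23 of 24. Settings in which they could not be fitted are not counted. Among these are the settings that remove their single CD value (without CD 1 or without CD 3, and measured in all 12 pools), so the counts do not test that value. Also not counted are the settings without UT 3 for miR-291b-5p and Ct under 32 for miR-135b-3p. Where a pool left out leaves 1 value in a group, it is assumed to vary like the other groups. In UT, miR-184-5p was kept in 20 of 27, miR-676-3p and miR-592-3p in 11 of 27, miR-758-5p in 10 of 27 and miR-291b-3p in 8 of 26. The filter of Ct under 32 left out miR-291b-3p. Over these settings the log2 fold change in UT ranged from 0.15 to 3.24 for miR-184-5p, 0.35 to 4.78 for miR-676-3p and 0.06 to 6.16 for miR-592-3p. It ranged from -6.77 to 0.13 for miR-758-5p and from 0.92 to 3.68 for miR-291b-3p. Of 6757 alternative values of the named microRNAs, 6585 kept their side of the threshold, 105 lost it, 66 gained it and 1 reversed: miR-758-5p in UT, 0.13 with the pairs of assays exchanged. Of the 6434 alternative values of microRNAs that did not pass with the main choices, 451 (7%) had the opposite sign. Counts are given in the order WL, UL and UT against CD, then UL against UT, WL against UL, WL against UT, early exposure and the 4 groups, and only where they moved by over 1.5 times or to or from 0; smaller moves, within 2 to 4 for WL and UL, 5 to 10 for UT, 2 to 3 for early exposure and the 4 groups and 3 to 4 for lists, are left out. The main counts were 3, 3, 7, 0, 0, 0, 2 and 2, with 4 lists.

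With RNU-43 as the reference, UL gave 5, UT 12 (12 higher, 0 lower, 6 of the main 7 among them), UL against UT 4, WL against UT 1, early exposure 6 and the 4 groups 10; the shift of all microRNAs in UT is part of this setting. The deposited values with a pseudocount of 1 or 16 gave 3 for UT and 1 for WL against UT. Since the deposited ratios grow with later cycles, a pseudocount flattens differences among microRNAs with an early Ct and changes those with a late Ct least. With Ct under 32, which leaves out 8 microRNAs, WL, UL, early exposure and the 4 groups gave 1 each. In a fit of the compared groups only, WL gave 1, UL against UT 5 and early exposure 9. Among microRNAs measured in all 12 pools, WL, UL, early exposure and the 4 groups gave 0 and UT gave 1, where 3 of 3 calls in WL and UL and 2 of 7 in UT were no longer tested. Sample weights gave 6, 6, 12, 7 for UL against UT, 7 for WL against UT, 7 and 14. Omitting both UT 3 and WL 3 gave 6 for UL against UT, 1 for WL against UL, 8 for WL against UT, 5 and 9. A covariate for UT 1 to 3 and WL 3, which rests on WL 3 against WL 1 and WL 2, gave 5 for UL, 22 for UT (6 higher and 16 lower, where the main calls were 6 and 1, with 2 of the main 7 among them), 16 for UL against UT, 1 for WL against UL, 23 for WL against UT, 19 and 22. Exchange of the paired assays gave 3 for UT. Subtraction of neighbouring assays gave 0 for UT, 1 for the 4 groups and 0 lists. Lists numbered 0 with an estimated correlation and 0 with the directional test of fry, whose mixed test gave the early-life nutrition list in UT an adjusted p of 0.0138. Beyond these constructions, the cause was not tested.

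Leaving out each pool gave 1 to 6 for WL (1 without UT 3, 6 without CD 3), 1 to 6 for UL (1 without UT 3, 5 without WL 3, 6 without CD 3), 1 to 11 for UT, 0 to 8 for UL against UT (4 without WL 2, 8 without WL 3, 1 without CD 1 or UL 1), 0 to 1 for WL against UL, 0 to 12 for WL against UT (12 without WL 3, 1 without CD 1 or UT 2), 1 to 9 for early exposure, 1 to 12 for the 4 groups and 0 to 4 for lists (0 without CD 1, CD 3, UT 1 or WL 3; 2 without UT 2 or UL 3). Pairing of the pools by replicate number was not shown and not excluded. Deviations of 18 pairs with the same number in different groups correlated at -0.27 to 0.26 (median 0.04, other pairs 0), and 7 of the 18 lay over 0.1. With the replicate block UT gave 4, UL against UT 1, the 4 groups 4 and the lists 1. No other count moved by over 1.5 times.

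DESeq2, its size factors, scaling to a library total and background subtraction were planned but not run, since the values are threshold cycles and the table lists no negative controls, and the setting without a filter removed nothing. For the comparisons of 3 against 3 pools the 10 splits are too few for a share under 0.05: the real counts were 3, 3, 7, 0, 0 and 0, and the highest other splits gave 0, 1, 1, 0, 0 and 0. Chance could not be excluded for early exposure (real 2, highest other 7; 6 of 100 drawn splits gave as many), the 4 groups (2; 3; 6 of 100) or the lists (4; 12; 28 of 100). The split with 7 microRNAs set the 3 UT pools against the CD and UL pools, and so follows the group UT; that with 12 lists joined CD 3, UT 1 and UT 2, then CD 2, UL 1 and UL 3, then CD 1, UT 3 and WL 1, then UL 2, WL 2 and WL 3, and so mixes the groups. The other splits gave a median of 2 lists with the preset correlation of 0.01, and at most 0 with an estimated correlation, so the list counts depend on that correlation, and a structure among the pools was not shown.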

Other observations

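The tests in this part were chosen after the results were seen, except that of the arms of a hairpin. Epithelial microRNAs were low in some UT pools: the mean level of the 9 epithelial microRNAs above the average level was 2.47 ± 0.99 in CD, 0.93 ± 0.66 in UT, 2.38 ± 0.40 in UL and 2.37 ± 0.74 in WL (SD, n = 3 pools each). MiR-141-3p, miR-200a-3p, miR-200b-3p, miR-200c-3p and miR-205-5p had UT 1 and UT 3 as their lowest pools of the 12, which held for 20 of all 466 microRNAs (4.3%); miR-183-5p, miR-203-3p, miR-375-3p and miR-429 did not show this. The pools of CD, UL and WL entered the choice of the first 5, since they had to lie above UT 1 and UT 3. Their deviations from the group means were not part of it. Within these groups the deviations of the 5 had a median pairwise correlation of 0.93, where random sets reach 0.45 (one-sided permutation p = 1e-04, the smallest that 10000 draws can give). No comparison was made with other sets from the 20 microRNAs lowest in UT 1 and UT 3. The p-value therefore does not account for how the 5 were chosen. The highest of 457 sets with the same spacing in accession order had 0.82, and with neighbours subtracted the 5 had 0.93. All 5 were lowest in CD 2, UL 2 and WL 1, so a source of these 5 that varies between pools, such as the amount of epithelial tissue taken with the fat or a shared control of these microRNAs, may underlie the low UT 1 and UT 3. The other 4 did not follow (correlation with the mean of the 5 of -0.24 to 0.28, with miR-429, from the cluster of miR-200a and miR-200b, at 0.28), the median over all 9 was 0.01 (random sets reach 0.21), so which source it is stays open, and the UL shift of the 9 was 6.3% of the UT shift (-73.1 to 85.6), too uncertain to judge exposure in utero.

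MiR-302c-3p and miR-302d-3p, of a cluster active in embryonic stem cells, came late in the control pools CD 1 and CD 2. MiR-302d-3p had Ct 33.12 and 35.04 there, 30.1 in CD 3 and 29.25 to 31.35 in the other 9 pools, and miR-302c-3p had 32 and 33.3, 28.45 in CD 3 and 27.95 to 30.49 elsewhere. Without CD 3, miR-302b-5p, miR-302c-3p, miR-302d-3p and miR-376b-5p passed the limma test in WL, UL and UT; with all pools 0 of them passed. These 4 assays lie within 7 places of each other in the order of 502 accession numbers. Over the 4 groups the members of the cluster had unadjusted p of 0.00689 (miR-302b-5p), 0.0373 (miR-302d-3p), 0.0437 (miR-302c-5p), 0.0727 (miR-302c-3p), 0.137 (miR-367), 0.256 (miR-302b-3p), 0.531 (miR-302a-3p), 0.562 (miR-367-5p) and 0.79 (miR-302d-5p) by the F test of limma (adjusted p 0.247 or more).

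Values of 2 pairs of assays may have been traded in UT 1, UT 2, UT 3 and WL 3. In these 4 pools 4 assays, miR-592-3p, miR-758-5p, miR-676-3p and miR-676-5p, stood apart from the other 8 by over 2 cycles. As a trade would give, each assay in the 4 pools lay within 0.42 cycles of its partner in the other 8, where 1.7% to 8% of assays lie as close. Each lay at least 3.59 from its own level, but a gap over 2 was part of the choice. Both pairs hold consecutive accession numbers, which 0.4% of random pairs would. MiR-676-3p and miR-676-5p are arms of 1 hairpin, and of 84 hairpins 29 have arms next to each other in that order. For this pair 0.4% is therefore too low a reference. Against exposure in utero as the cause, which UL and WL share, the largest UL shift was 14.2% of the UT shift. Upper bounds at 2 SE were 11.1% to 29.4%. The same 4 assays were found when they were chosen on these 4 pools against CD alone, with UL left out. The shift of WL 1 and WL 2 was -3.8% to 6.1% of the UT shift. An effect of exposure that ends at birth, as in UT alone, stays open for the UT pools. By itself it does not account for WL 3, whose exposure went on to the end of the experiment. In the order named, the 4 assays lay at 0.46, -4.48, 1.04 and -2.4 in WL 3. They lay at 0.19, -4.66, 1.55 and -1.97 in UT. Such an effect would also need WL 3 to be a mislabelled UT pool. A mislabelled WL 3 stays open as well, since over the other microRNAs its mean correlation with the UT pools was -0.14 (-0.36 to 0.11), that of WL 1 and WL 2 was -0.17, and the UT pools had 0.05 with each other (-0.08 to 0.17).

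MiR-494, miR-291b-5p and miR-20b-5p were late or missing in CD 1 to 3 and UT 1 and UT 2 and came earlier in the other 7 pools, with UT 3 between for miR-494 (Ct 22.99, against 25.11 in CD 1 and at most 20.04 in UL and WL) and miR-20b-5p (31.59, against 34.53 and at most 30.22). The 3 assays span 3 places in the order of accession numbers, where random sets of 3 span a median of 247 of 496 (one-sided permutation p = 1e-04, the smallest that 10000 draws can give), so a failure of assays side by side on the plate is a candidate explanation. Whether high-fat diet at any time raises these microRNAs stays open, since 6 of 6 values in UT 1 and UT 2 are missing, which a failed assay gives too (chosen on CD, UL and WL alone, the assays were these 3 and miR-135b-3p, the last with UT 1 and UT 2 at Ct 32.11 and 32.2, near UL), and so does a rise with exposure through lactation, with UT 3 as the exception.

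Assays with neighbouring accession numbers deviated together across the 12 pools: over 458 microRNAs the median correlation was 0.47 for direct neighbours, fell to -0.15 at a gap of 15 and came back to 0.2 at a gap of 30, where random orders reached at most 0.1 (permutation p = 0.001, the smallest that 1000 orders can give). Members of a microRNA family listed together do not account for it, since 399 neighbouring pairs of different families had a median of 0.44 (random orders reach 0.04). Missing values clustered as well: 17 of 55 lay next to another missing value of the same pool, where random orders gave a median of 1 and at most 6. The missing values of miR-494, miR-291b-5p and miR-20b-5p in UT 1 and UT 2 contribute to this count, so it is not independent of the short span of these assays. Position on the plate is a candidate explanation, if assays were laid out in accession order with a repeat of about 30. The layout is not given in the sources used here, so this was not tested directly. With neighbours subtracted (which leaves a correlation of -0.16 between neighbours), miR-291b-5p and miR-135b-3p still passed in WL, UL and early exposure. The first had log2 fold changes of 4.68, 4.82 and 4.83 in place of 8.22, 8.30 and 8.07. In UT 0 passed: 5 of the 7 had log2 fold changes of 3.32 or more in size at an adjusted p of 0.0595, among them miR-291b-5p at 4.83 in place of 7.84, and miR-184-5p and miR-291b-3p fell from 2.50 and 2.94 (SE 0.43 and 0.62) to 1.43 and 0.92 (SE 0.82 and 0.95).

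The 5p and 3p arms of 84 hairpins had a median correlation of 0.13 across pools (one-sided permutation p = 0.0055), which met the prediction written beforehand for a shared transcript. In a comparison added after that result was seen, neighbouring assays of different hairpins had 0.48, and 29 of the arm pairs are themselves neighbours. Arm pairs that are not neighbours were not tested alone, so a shared transcript and the place on the plate were not told apart. Neighbouring pools of different groups in sample order had a median correlation of -0.07 over 3 pairs, against 0.01 for other pairs. These deviations were taken from each group's own mean, and a steady drift would put neighbours across a group border on opposite sides of it. The comparison therefore cannot decide on drift in sample order.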
